A study of Populus tomentosa with 12 samples.

How the data were processed

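RNA was sequenced from roots and shoots of Populus tomentosa (Chinese white poplar), propagated in vitro and moved to a nutrient solution holding either 100 µM Fe (Fe-sufficient) or 0 µM Fe (Fe-deficient). Per the labels' protocols, plants grew at 24 °C with 16 h of light per day and had shoots of about 10 cm when selected. Also listed for all 12 libraries are a photon flux of 50 µmol per m2 and s, 1.5% sucrose and 1 mg/L NAA. The length of the Fe treatment is not given in the sources used here. The 12 libraries form 4 groups of 3, and the labels' protocols call the replicates biological, without saying which plants went into each. Root replicates were numbered 1 to 3 in accession order, and shoot replicates carry the numbers of their titles. Fe-sufficient shoot libraries are titled CK and Fe-deficient ones WT, which the labels do not explain. Groups were taken from the labels' characteristics, on which the direction of every shoot change rests.

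The deposited files hold raw counts of reads per gene ID, one file per library, which the authors made and did not normalise. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.0.5, HTSeq 2.2.1 and edgeR 3.16.5 were used. Their settings, the genome build, the annotation and the strand setting of the counter are not given in the sources used here. Each file lists 42950 gene IDs and 5 rows of reads that the counter gave to no gene. These rows stayed out of library sizes and tests. They held 58.3% to 64.0% of all reads listed in root libraries and 72.6% to 73.1% in shoot libraries.

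None of the 42950 gene IDs matched the 60139 genes of the P. tomentosa reference table (assembly PTv2), and the files do not pair IDs with names. The 44 gene lists fixed before the data were examined (iron uptake, photosynthesis, hormones and others) were defined on gene descriptions, so none of them was tested. The lists would need an annotation that holds these IDs with descriptions, which was not used here. No coordinates or sequences were used, and genes with near-identical copies or overlapping neighbours could not be identified. The rule for named genes, also fixed before the data were examined, then allowed per tissue the 2 IDs that rose most and the 2 that fell most. They had to be past the threshold, have a mean of at least 1 CPM (TMM-normalised counts scaled to a library total of 1e6), and have replicates that did not overlap between the groups.

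Each tissue was tested on its own 6 libraries with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with robust estimation, TMM normalisation and edgeR's filterByExpr (default minimum count 10). Benjamini-Hochberg adjusted p under 0.05 was the threshold, at any fold. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. The difference between the root response and the shoot response was tested as a contrast of 4 groups in 1 fit of all 12 libraries, with the same tool. Overlap of calls between tissues was tested with Fisher's exact test (two-sided) and by 10000 permutations of the shoot calls within joint deciles of abundance in the tissues. These designs were fixed before the data were examined, except for the abundance-matched permutations. Measures of single libraries were compared with two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1.

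After the data were examined, tissue-specific gene classes were defined. A gene was shoot-specific where its mean over the 6 shoot libraries was at least 10 CPM and at least 20 times the sum of its root mean and 0.5 CPM. Root-specific genes were defined the other way round. CPM in these definitions, and shares of gene counts, were taken without TMM. Classes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and with an estimated one.

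The same code was tested on simulated data. Counts were drawn from the real means, spreads and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold. Each gene was drawn on its own, so the simulated data hold no correlation between genes and no outlying library. For the difference between tissues only root levels were changed. The changed genes were drawn from those with a mean of at least 2 CPM, so the recovered shares do not cover lower genes. In the root simulation of 23453 genes, 31% of the 2-fold and 87% of the 4-fold changes were recovered, and 10 of 128 calls were false. In the shoot simulation of 21314 genes the recovered shares were 35% and 87%, with 12 false calls of 134. For the difference between tissues, over 24737 genes, they were 5% and 61%, with 6 false calls of 72.

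Alternatives were DESeq2 1.42.0, RLE size factors, no filter or a filter of at least 1 CPM in 3 libraries, stricter thresholds, 1 fit of all 12 libraries, leaving out each replicate, and the title number of the shoots as a replicate block. The filter of at least 1 CPM used CPM without TMM. No replicate pair was a duplicate. The chi-square of counts per degree of freedom lay between 6.23 and 23.8 over the 12 pairs within groups. Counting intervals and floors (3 counts for a group at 0) cover counting error only.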

Results

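Transcript levels were measured by RNA sequencing in roots and shoots of poplar plantlets grown with or without iron. The plants fall into 4 groups of 3 libraries, by tissue and by Fe supply. Root libraries held 8663523 to 10886552 reads counted in genes, and shoot libraries 5360670 to 6149779. Root libraries detected 28923 to 29512 of the 42950 listed genes with at least 1 count, and shoot libraries 27402 to 28215. A set of 69 genes reached at least 1 CPM (here without TMM) in every root library and had 0 counts in all shoot libraries. The reverse held for 189 genes.

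The tissues also differed in how reads were assigned. Of the reads counted in 1 gene, in no gene or as ambiguous, 1.25% to 1.41% fell in no gene in root libraries and 49.5% to 50.0% in shoot libraries. Ambiguous reads made up 5.12% to 6.40% of reads in genes in roots, and 1.89% to 2.79% in shoots. Fe supplies were compared within each tissue, as fixed beforehand, and levels were not tested between tissues. Counts of genes seen in 1 tissue, and the classes of tissue-specific genes, set levels across these differently assigned libraries.

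**Figure D1:**
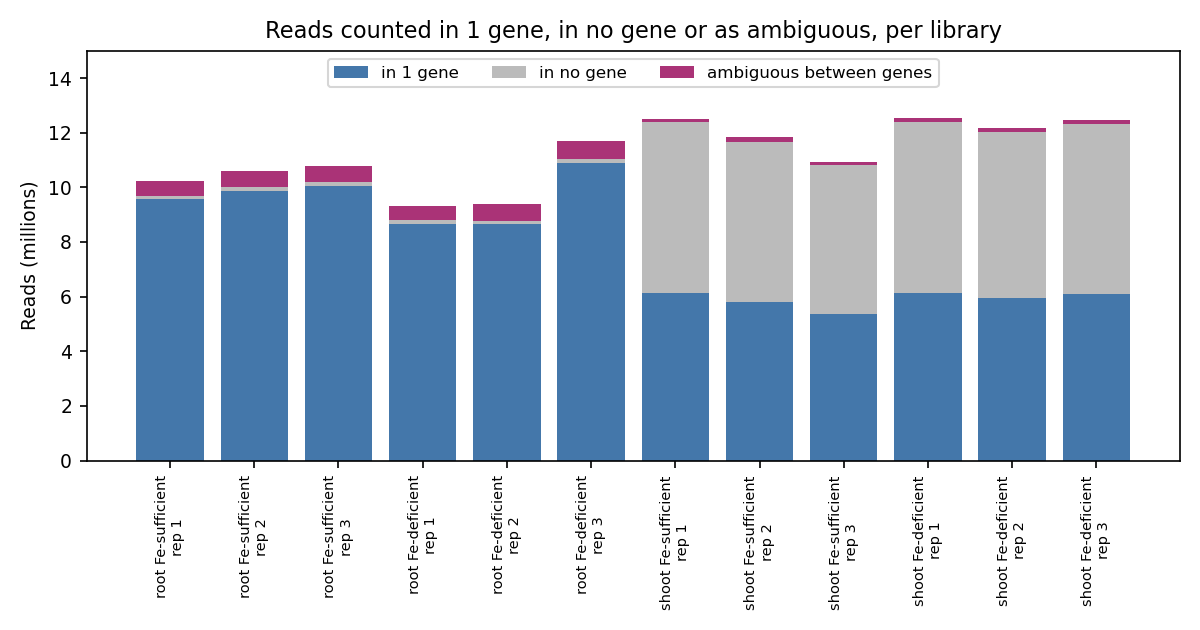
Reads (y axis, in units of 1e6) counted in 1 gene, in no gene or as ambiguous between genes, stacked per library for the 6 root and 6 shoot libraries. The part in no gene is 1.25% to 1.41% in roots and 49.5% to 50.0% in shoots.

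Within each tissue, 5 measures of the libraries were compared between Fe supplies. In shoots, 3 of them did not overlap between the groups. The 10 most abundant genes of each library took 5.54% ± 0.317 (SD, n = 3) of gene counts in Fe-deficient shoots and 8.13% ± 1.09 (SD, n = 3) in Fe-sufficient shoots. Reads in no gene made up 50.0% ± 0.0414 and 49.8% ± 0.266 (SD, n = 3 each), and unaligned reads 15.8% ± 0.287 and 14.8% ± 0.479 of all reads (SD, n = 3 each). For each of the 3 the two-sided exact permutation p was 0.1 (0.333 adjusted over 10 such comparisons), the smallest this design allows. In roots the share of the 10 most abundant genes was 2.29% ± 0.268 without Fe and 2.23% ± 0.233 with Fe, with an exact permutation p of 1.

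The first comparison asked which genes respond to Fe deficiency in roots. Of 23785 tested genes, 46 rose and 88 fell in Fe-deficient roots (edgeR's quasi-likelihood test, adjusted p under 0.05). The median log2 fold change was 1.81 among the genes that rose and -1.41 among those that fell. Changes of at least 4-fold were found in 20 genes that rose and 22 that fell, and changes of at least 8-fold in 9 and 6 genes. The genes that rose had a median level of 21.8 CPM, and those that fell one of 39.3 CPM, against 16.9 CPM over all tested genes.

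The genes that rose most in roots were nearly silent with Fe. Potri.004G193400 had 781 counts over the 3 Fe-deficient root libraries and 1 count over the 3 Fe-sufficient ones, a ratio of 816 with an exact 95% counting interval of 146 to 32300. Its level without Fe was 21.2, 8.98 and 46.2 CPM in the 3 replicates. Potri.005G097900 went from 1 count to 462, a ratio of 482 (interval 86.2 to 19100), and reached 15.3 ± 9.24 CPM (SD, n = 3). Their adjusted p by edgeR was 0.0272 and 0.0210. In shoots, Potri.004G193400 had 0 counts and Potri.005G097900 had 5 counts over the 6 libraries, too few for either to be tested. Without Fe-sufficient replicates 1, 2 or 3 or Fe-deficient replicate 1, neither gene passed the threshold (adjusted p by edgeR 0.0564 to 0.133). Their log2 fold changes in these runs were 8.61 to 10.9 and 7.88 to 10.2, against 9.08 and 8.34 with all libraries.

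The largest falls in roots were those of Potri.018G106000 and Potri.002G069400. Potri.018G106000 had 71 counts over the Fe-sufficient and 1 over the Fe-deficient root libraries (ratio 0.0147, exact 95% counting interval 0.000367 to 0.0846; adjusted p by edgeR 0.0311). Potri.002G069400 fell from 14.9 ± 6.26 to 1.13 ± 0.301 CPM (SD, n = 3 each), a log2 fold change of -3.71 ± 0.426 (SE; adjusted p by edgeR 0.0210). Its log2 fold change in shoots was -3.36 ± 0.797 (SE) and did not pass the threshold there (adjusted p by edgeR 0.0819). In roots, the call of Potri.018G106000 was lost without any 1 of the 6 libraries (adjusted p by edgeR 0.0519 to 0.133). The call of Potri.002G069400 was lost without any 1 of them except Fe-sufficient replicate 3 (0.0537 to 0.122). Over the 6 omissions the log2 fold change was -7.59 to -5.11 for Potri.018G106000 (-5.67 with all libraries) and -4.02 to -3.47 for Potri.002G069400.

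**Figure D2:**
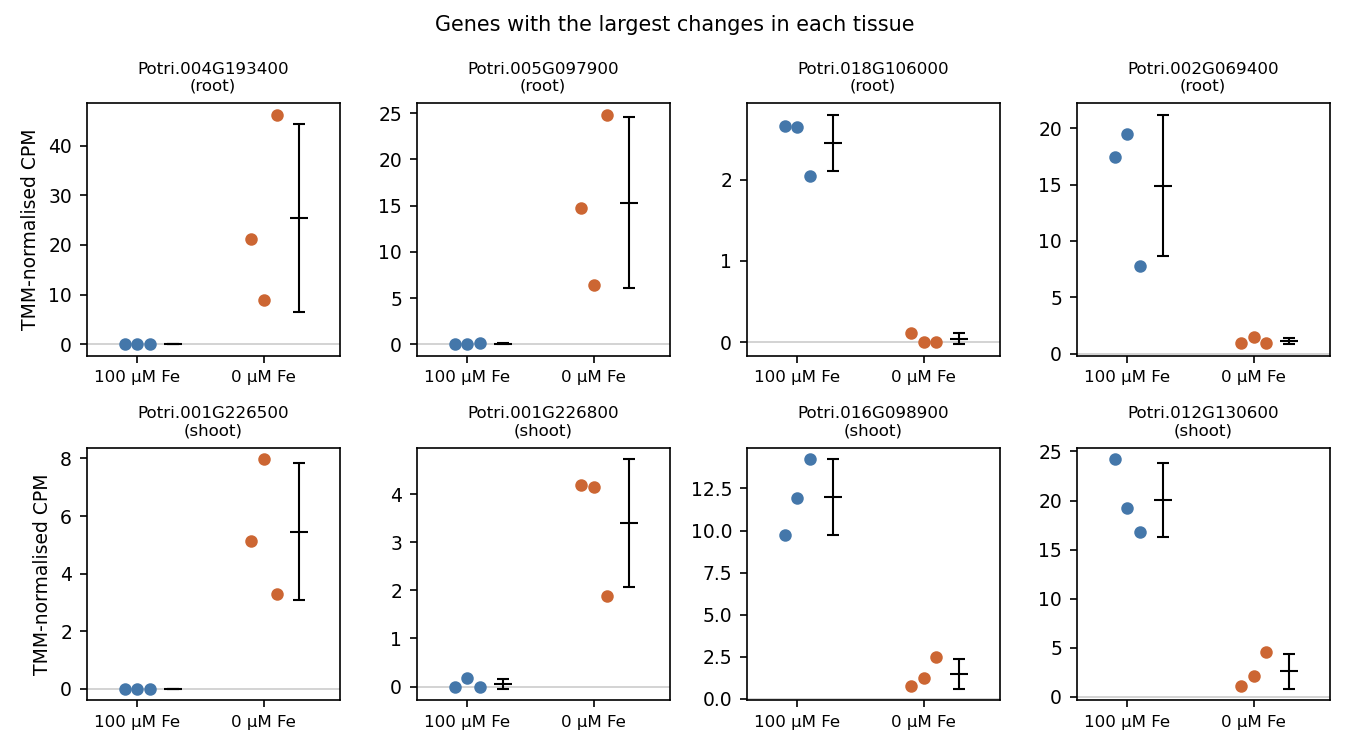
TMM-normalised CPM (linear axes) of the 2 genes that rose most and the 2 that fell most in roots (top) and in shoots (bottom). Coloured points are replicates at 100 µM or 0 µM Fe, and the black mark and bar are the mean ± SD of n = 3; the replicates of the groups do not overlap in any panel.

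In roots, 3622 genes (15.2% of those tested) had an unadjusted p under 0.05, where chance gives 5% on average. The replicates of the groups did not overlap in 21.4% of tested genes, where chance gives 10% on average. Correlated genes can move both shares away from these averages in a single grouping, and no other grouping was set beside them here. The number of root calls changed when a library was left out and with the fit. It was 19, 0 and 71 without Fe-sufficient replicates 1, 2 and 3, and 3, 20 and 30 without Fe-deficient replicates 1, 2 and 3 (without Fe-sufficient replicate 2, edgeR still gave 2912 genes an unadjusted p under 0.05), while DESeq2 called 1109 genes, of which 437 rose, and 1 edgeR fit of all 12 libraries called 508, of which 254 rose. Without Fe-deficient replicate 2, 12 of the 20 calls rose. Leaving out any library also lowers the power of the test, which was not separated from the part of single libraries.

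The second comparison asked the same of shoots. Of 21665 tested genes, 252 changed in Fe-deficient shoots (edgeR's quasi-likelihood test, adjusted p under 0.05), of which 137 (54.4%) rose and the others fell. The rises were larger than the falls in size, with median log2 fold changes of 1.67 and -1.07. At least 4-fold changes were found in 51 genes that rose and 10 that fell, and at least 8-fold changes in 10 and 0. The genes that fell were abundant ones. Their median level was 145 CPM, against 23.8 CPM for genes that rose and 15.8 CPM over all tested genes, and 71 of them lay above 100 CPM. The TMM factors were 0.889 to 0.960 in Fe-sufficient and 1.055 to 1.101 in Fe-deficient shoots, so the balance of rises and falls rests on this scaling. With RLE size factors in its place, 140 of 252 calls rose.

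The genes that rose most in shoots are listed near each other in the files, with other genes between them: Potri.001G226500 and Potri.001G226800. Potri.001G226500 had 0 counts in the 3 Fe-sufficient shoot libraries and 106 counts in the 3 Fe-deficient ones, where it reached 5.46 ± 2.37 CPM (SD, n = 3). With a floor of 3 counts over the Fe-sufficient group it was 33.7-fold higher without Fe (adjusted p by edgeR 0.00481). The lower limit of its exact 95% counting interval was 26.9-fold. Potri.001G226800 had 1 and 66 counts, a ratio of 62.9 (exact 95% counting interval 10.9 to 2520; adjusted p by edgeR 0.0116). Its call was lost without Fe-sufficient replicate 1 and Fe-deficient replicates 1 and 2 (adjusted p by edgeR 0.0696, 0.0863 and 0.0876). Its log2 fold change was then 4.90, 5.18 and 5.19, against 5.36 with all libraries. Whether Potri.001G226500 and Potri.001G226800 are near-identical copies that share reads was not analysed here. The largest falls were those of Potri.016G098900, from 9.72 to 14.2 CPM in the Fe-sufficient replicates to 1.50 ± 0.892 CPM, and Potri.012G130600, from 20.1 ± 3.80 to 2.59 ± 1.76 CPM (SD, n = 3 each). Their log2 fold changes were -2.98 ± 0.390 and -2.95 ± 0.390 (SE), with adjusted p by edgeR of 0.00355 and 0.0044. Without Fe-deficient replicate 2 the adjusted p of Potri.012G130600 by edgeR was 0.0535.

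Genes expressed mainly in shoots were then taken as a class. A set of 534 shoot-specific genes, defined after the data were examined, took 20.4% ± 2.06 of gene counts in Fe-sufficient and 15.1% ± 0.284 in Fe-deficient shoots (SD, n = 3 each; two-sided exact permutation p 0.1). The share changed by -5.26 percentage points without Fe-sufficient replicate 2, and by -5.32 with it. It changed by -2.66 without the 10 most abundant members (from 12.4% to 9.76%) and by -1.42 with a class of at least 50-fold (190 genes), both chosen after the data were examined. Classes of unlike size hold unlike shares of counts, so these points do not compare the strength of the change. Of the 533 tested members of the 20-fold class, 29 fell, 8 rose and 496 did not pass the test. A log2 fold change below 0 was found in 427 of them (80.1%). The median was -0.29. The class was lower by camera with the preset correlation (adjusted p = 4.99e-13 over 4 set tests), and did not pass with an estimated correlation (adjusted p = 0.149 with an estimated correlation). The 424 root-specific genes took 0.0875% ± 0.0209 of the counts of Fe-sufficient and 0.129% ± 0.0428 of those of Fe-deficient shoots (SD, n = 3 each; exact permutation p 0.3).

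**Figure D3:**
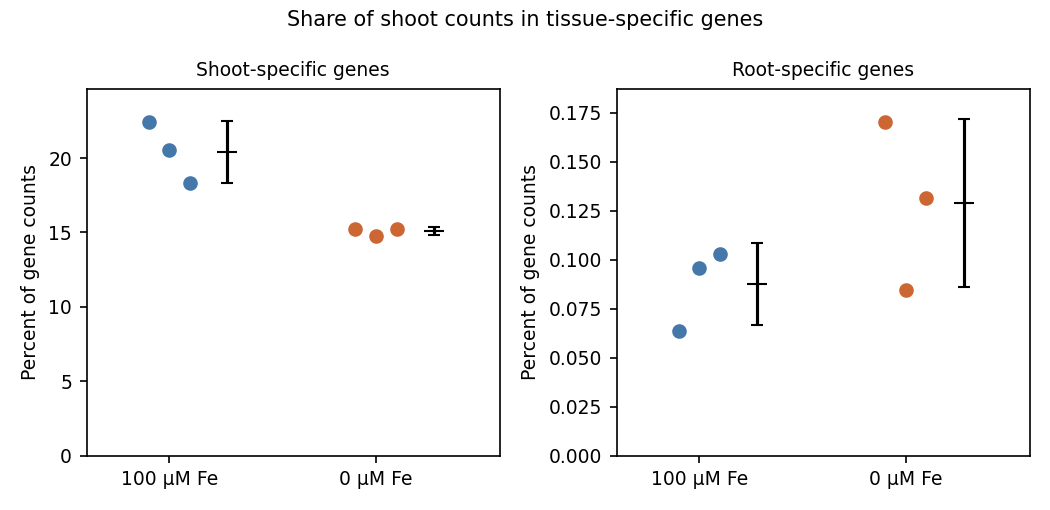
Percent of the gene counts of each shoot library that fell in the 534 shoot-specific (left) and 424 root-specific genes (right). Points are replicates at 100 µM or 0 µM Fe, black marks and bars the mean ± SD of n = 3; the shoot-specific share is 18.3% to 22.4% with Fe and 14.8% to 15.3% without.

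In shoots, 1970 genes (9.09%) had an unadjusted p under 0.05, and the groups did not overlap in 14.5% of tested genes. Fe-sufficient replicate 2 stood apart from the other shoot libraries on the first principal component (32.6% of the variance), with a mean Spearman correlation to its group of 0.943. The number of calls was 571 without that library, of which 40.1% rose. It was 114 (62.3% rose) without Fe-sufficient replicate 1, and 64 (76.6%), 72 (81.9%) and 127 (66.1%) without Fe-deficient replicates 1, 2 and 3. DESeq2 called 517 genes, of which 46.6% rose, and 1 edgeR fit of all 12 libraries called 194, of which 47.9% rose. With the title number as a replicate block edgeR called 134 (65.7% rose), and with no filter on low counts 437 (50.1% rose).

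The third comparison asked whether the responses of roots and shoots share genes. Of 20269 genes tested in both tissues, 9 were called in both. In both tissues 5 genes rose, where independent lists give 0.247 (Fisher's exact test, p 4.56e-06, 1.82e-05 adjusted over 4 combinations of direction). With shoot calls permuted among genes of like abundance, 0.398 such genes came out on average, and the p was 1e-04, the smallest that 10000 permutations can give. The Fisher and permutation p-values of the overlap treat genes as independent, so they do not measure the spread between replicates. Both tissues showed a fall in 2 genes (0.364 for independent lists; Fisher's exact p 0.0515, adjusted 0.0687; permutation p 0.0406 at like abundance, adjusted 0.0812). A further 2 genes rose in roots and fell in shoots (0.205 for independent lists; adjusted Fisher's exact p 0.0358, but permutation p 0.281 at like abundance). No gene fell in roots and rose in shoots by edgeR, while DESeq2 gave 22 such genes.

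The signs of the responses were also compared, with the 9 shared genes included. Of the 111 root calls tested in shoots, 61 (55.0%, exact 95% interval 45.2% to 64.4%) had the same sign there. Of the 229 shoot calls tested in roots, 99 (43.2%, interval 36.7% to 49.9%) had the same sign, against 48.5% of all 20269 genes tested in both. Pearson's r of the log2 fold changes was 0.317 and Spearman's rho 0.108 across the root calls, -0.0554 and -0.125 across the shoot calls, and -0.0406 and -0.043 across all genes tested in both; genes are not independent replicates, so these values and intervals are descriptions. With DESeq2, all 4 combinations of direction held more genes than independent lists give (16 rose in both, 17 fell in both, 15 rose in roots and fell in shoots, and 22 did the reverse). The number of genes changed in the same direction was 7, and it was 2, 0, 0, 2 and 2 without root Fe-sufficient replicates 1 and 2 and root Fe-deficient replicates 1, 2 and 3, and 2 and 3 without shoot Fe-deficient replicates 1 and 2.

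**Figure D4:**
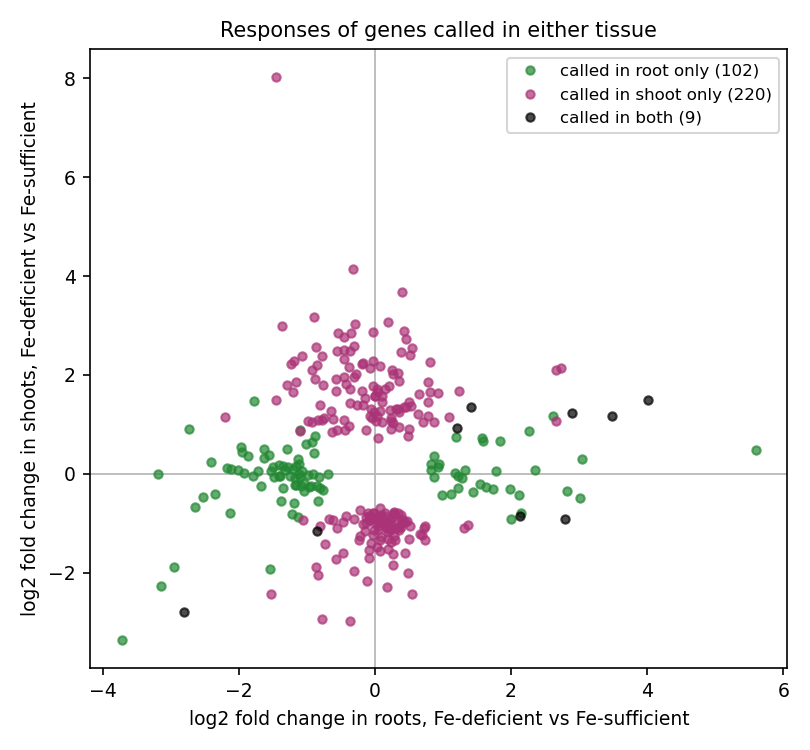
Log2 fold change (Fe-deficient against Fe-sufficient) in roots on the x axis and in shoots on the y axis, for genes tested in both tissues and called in at least 1. Each point is a gene, coloured by where it was called; of the 9 genes called in both (black), 7 changed in the same direction.

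The fourth comparison tested the difference between the responses itself. Of 25046 genes tested in the fit of all 12 libraries, 313 responded differently in roots and shoots (edgeR's quasi-likelihood test, adjusted p under 0.05). For 164 of them the root response was the higher one, and for 149 the lower. Of the 313 genes, 44 had been called in roots alone, 5 in both tissues and 159 in neither, and the others in shoots alone. In 284 of them the fitted responses had opposite signs, which selecting genes for a large difference favours by itself. Among the named genes, the rise of Potri.001G226800 in shoots exceeded its fitted root response, which rests on 35 counts over the 6 root libraries (log2 difference, root minus shoot, -6.39 ± 1.24, SE; adjusted p by edgeR 0.0279). The fall of Potri.016G098900 in shoots also differed from its root response (2.63 ± 0.494, SE; adjusted p by edgeR 0.0237), whose own log2 fold change was -0.37 ± 0.267 (SE). For Potri.012G130600 the difference was 2.18 ± 0.537 (SE) and missed the threshold (adjusted p by edgeR 0.0723). For Potri.002G069400, which had fitted falls in both tissues, it was -0.32 ± 1.15 (SE; adjusted p by edgeR 0.963). The count of 313 was 116, 203 and 164 without root Fe-sufficient replicate 2 and root Fe-deficient replicates 1 and 2, and 135 and 147 without shoot Fe-deficient replicates 2 and 3, while without shoot Fe-sufficient replicate 1 and shoot Fe-deficient replicate 1 the called share went from 1.25% to 0.467% and 0.401% of tested genes. DESeq2 called 855 genes.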

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

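These tests were planned before the data were examined. The number of genes whose response to Fe deficiency differed between roots and shoots was 313. In 60 splits of the Fe labels within tissues, the real one included, 1 gave as many calls, the real one itself. The highest of the other splits gave 81. A share of 1 in 60 lies under 0.05, so a random grouping rarely gives this count, but 60 splits cannot exclude it. The other splits also mix the Fe supplies, so an Fe effect within a tissue widens their spread and lowers their calls. For the single tissues the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 134 calls in roots and 252 in shoots, each the only 1 of 10 splits to reach its count, and the highest of the other splits gave 0 and 1.

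A difference between the tissues was found for 3 of the named genes. The log2 difference (root response minus shoot response) was -10.11 for Potri.001G226500, -6.39 for Potri.001G226800 and 2.63 for Potri.016G098900, with adjusted p by edgeR of 0.00637, 0.0279 and 0.0237. The size of the first depends on the prior count of the fit, since all 3 Fe-sufficient shoot libraries had 0 counts, and the second rests on 1 count in those libraries. The log2 fold change of Potri.001G226500 in roots was -1.45 ± 0.581 (SE; adjusted p by edgeR 0.294).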

How the results depend on the processing

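DESeq2 called 1109 genes in roots (134 by edgeR, all among them), 517 in shoots, 855 (3.41% of tested genes) for the difference between tissues and 33 changed the same way in both tissues. With no filter on low counts, roots gave 357 and shoots 437 calls. At an adjusted p under 0.01 the counts by edgeR were 0 in roots (3622 genes at an unadjusted p under 0.05), 83 in shoots, 56 (0.224%) for the difference and 0 shared. One fit of all 12 libraries called 508 genes in roots, of which 125 were among the 134. Leaving out 1 replicate gave 0 to 71 calls in roots (2912 genes at an unadjusted p under 0.05 where it gave 0), 64 to 571 in shoots, 0.401% to 1.06% of tested genes for the difference (1.25% with all libraries) and 0 to 8 shared. The deviations of same-numbered shoot libraries from their group means correlated at -0.16, 0.0026 and 0.12, so their numbers were not taken as a pairing, and not every library correlated best with its own number; with the number as a replicate block, calls were 134 in shoots and 166 (0.663%) for the difference. The cause of these changes was not tested. The other settings run for each count stayed within 1.5 times; for shared genes these did not include RLE size factors, other filters or 1 fit of all libraries. The named genes kept their call in 88 of 116 alternatives, lost it in 28 and reversed in 0. Shares of shoot-specific counts changed by -7.52 and -1.42 percentage points with classes of at least 10-fold and 50-fold, chosen after seeing the data. These classes hold 925 and 190 genes, so the points do not compare the strength of the change. Gene lists were not run, with any alternative, since no ID matched the reference table used; another annotation of these IDs was not used here. Simulations at the real library sizes and spreads drew genes independently of each other. They recovered 31% to 35% of 2-fold changes in roots and shoots, among genes with a mean of at least 2 CPM. Depth was not varied, so its part in this was not separated from the spread between replicates.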

Other observations

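The tests of strand setting, genomic DNA, transcription outside genes, root tissue and the outlying library were chosen only after their results were seen, and the gene classes and neighbouring pairs were defined after the data were examined.

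Tissue-specific genes were also examined in the tissue where they are low. Of the shoot-specific genes, 220 had enough counts for a test in roots. There 4 rose and 216 did not pass the test, with a median log2 fold change of 0.33, and 57 of the 220 were below 0. Camera called this set higher in Fe-deficient roots with the preset correlation (adjusted p = 1.3e-09 over 4 set tests) but not with an estimated one (adjusted p = 0.0772). All 534 shoot-specific genes together took a share of root counts of 0.358% ± 0.0366 with Fe and 0.464% ± 0.0268 without (SD, n = 3 each; exact permutation p 0.1). Of the root-specific genes, 155 were tested in shoots, where 1 rose and 154 did not pass, with a median of 0.40 (adjusted p = 8.45e-07 with the preset and 0.352 with an estimated correlation). In roots themselves the 424 root-specific genes had a median of -0.04, with 1 that rose and 8 that fell (adjusted p = 0.0556 and 0.424).

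The first pattern is the lower share of shoot-specific genes in Fe-deficient shoots, which dropped by 5.32 percentage points. Its 10 most abundant members carried a large part of it, but without them the share still changed by -2.66 percentage points, from 12.4% ± 1.02 to 9.76% ± 0.0945 (SD, n = 3 each). The median log2 fold change of the class, -0.29, lay below all 10000 random lists of like abundance (-0.08 to 0.02). These lists were drawn gene by gene and do not carry the inter-gene correlation of the class (0.112), so their range is too narrow for a test. The outlying Fe-sufficient replicate 2 does not account for the lower share, since the change was -5.26 without that library. Root tissue would have to make up 25.2%, 27.7% and 25.3% of Fe-deficient replicates 1, 2 and 3 to dilute the share this far. It would add 1.16%, 1.28% and 1.17% of counts in the 424 root-specific genes. The excess found was 7.11%, -0.213% and 3.79% of that. Root-specific genes had to be low in the mean of all 6 shoot libraries, the Fe-deficient ones included. But root tissue would raise all genes expressed in roots, so leaving out raised genes would not have kept these 424 low. For these genes the values argue against root tissue in this amount. This holds if that tissue resembled the sequenced roots and its genes were counted alike in shoot libraries. Smaller amounts stay open. A response of the shoot-specific genes as a group to Fe supply may be the cause and stays open as a hypothesis. Camera with an estimated correlation gave an unadjusted p = 0.0745. The bound set before this test, but after the data were examined, took a p above 0.05 as evidence against. That bound was badly chosen, since with 6 libraries and an inter-gene correlation of 0.112 a missed threshold does not show absence. Sampling of another shoot part, or at another time of day, was not tested.

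The second pattern is the share of reads in no gene, 49.5% to 50.0% in shoots and at most 1.41% in roots. Genomic DNA would fall on all genes alike, yet 11314 genes (26.3%) had 0 counts over the 6 shoot libraries. But 8962 genes had 0 counts in all 12 libraries and may be ones that no read could be counted in, so the 26.3% cannot decide. The 69 genes with at least 1 CPM in every root library could be counted there, and had 0 counts in all shoot libraries. For these 69 genes the values argue against DNA reads. A candidate explanation is that shoot libraries that do not mark strand were counted with a strand setting and root libraries without one: every shoot library lay within 0.544 percentage points of 50%, and ambiguous reads were fewer in each shoot library than in each root library. Shoot transcription outside annotated genes cannot be told apart from this, because tissue and processing coincide, although the range over the 6 shoot libraries was only 0.582 percentage points. Comparisons of Fe supply within a tissue do not mix the kinds of library, but the tissue-specific classes are defined across them and rest on this open point.

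The third pattern is that genes listed next to each other were called together in shoots. Of 12427 pairs of adjacent tested genes, 6 were called in the same direction, against 0.86 with gene order shuffled (permutation p 5e-04 over 10000 shuffles), and 1 of 14348 pairs in roots (0.252 with shuffled order; permutation p 0.224). Adjacent rows may move together in any grouping of the libraries: across genes, the correlation of neighbours' log2 fold changes was 0.0734 in shoots and 0.109 in roots, and the other 9 splits of the libraries reached 0.0898 and 0.127. As 2 of the 9 other splits in shoots and 3 in roots were as high, a link of neighbouring genes to Fe supply cannot be told apart from this general property, nor from reads shared between similar copies.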
